A study of Homo sapiens with 2 samples.

How the data were processed

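Total RNA of C4-2B and C4-2B-MDVR cells, 1 sample each, was isolated with Trizol, amplified, fragmented, biotin-labelled and hybridized to Affymetrix arrays, per the labels' protocols. The deposited values are intensity values on a linear scale, as their range shows, and the authors' background correction, normalization and summarization are not given in the sources used here. No step was undone. The values were used as deposited and log2 was taken, so each difference is log2 intensity in C4-2B-MDVR minus log2 intensity in C4-2B. The table held 54675 probe sets and 0 sample columns besides these. Pearson's r of log2 values across all probe sets of the 2 arrays was 0.978 (Spearman's rho 0.978). Probe sets are not independent replicates, so this describes the arrays only. The median difference over all probe sets was 0.04.

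Probe sets were named by the platform annotation of 2016, which lists 42898 of them, 41097 with 1 gene symbol and 1801 with several. The remaining 11777 are unnamed here. Symbols were checked by Entrez identifier against NCBI RefSeq genes of GCF_000001405.40 (GRCh38.p14). Of the single-symbol probe sets 41043 matched and 0 symbols changed. No coordinates are given because the sources used here name no build, and the reference served only for names, gene types and gene order. Probe sets with several symbols named no gene. Where a gene had several probe sets, the one with the highest mean over both arrays stood for it. Some genes of the fixed lists and of the named set are not reported here.

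A gene counted as above the detection floor when its value on the brighter array was at or above that array's median log2 intensity (5.39 for C4-2B and 5.44 for C4-2B-MDVR), since the deposited table used here has no detection calls. Where the dimmer array was under its floor, a bound ("at least N-fold") is the brighter value against the dimmer array's floor. Genes with a log2 difference of 1 or more in size were counted as 2-fold or more higher or lower, from measured values. With 1 array per line no test of significance is possible, and no p-value, SE or SD is given for any gene.

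Before the data were examined, 30 gene lists were written, along with the threshold, floor, rule for named genes and alternatives. For each list the median difference of members above the floor was placed among the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean level. A list stood apart when its median fell among the outermost 2.5% of random medians at either end, so 5% of lists of unrelated genes would do so by chance. This describes these 2 arrays and is no test of the cell lines. Named genes were the 15 protein-coding genes with the largest difference in each direction, leaving out noncoding, immune receptor and clone symbols, the up to 6 members of each list with the largest absolute difference, and a fixed set of androgen response, steroid synthesis, lineage and drug resistance genes. Members named beyond these were chosen after their values were seen.

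Alternatives were other scalings (median centring, quantile normalization, loess with a span of 0.3), the mean of a gene's probe sets, floors at the 25th and 75th percentile or none, thresholds of 1.5-fold and 3-fold, probe sets with several symbols, and list tests with 5 bins, no matching, the mean, or members left out. The mean of a gene's probe sets took in those under the floor. The steps were tested on simulated differences, drawn with the middle spread of the measured differences at each level and run on 13437 genes of this comparison. Of simulated 2-fold differences 56% were called and of 4-fold ones 100%, and 1.08% of unchanged genes were called. The simulated 2-fold differences lay at the cut-off itself, so a share of about this size follows from it and is no detection rate. Simulated lists of 20 genes stood apart in 5% of cases when unshifted and in 84% when shifted by 0.25. The unshifted lists were random genes, so 5% follows from the cut-off and does not cover genes regulated together. The simulated noise came from these 2 arrays without replicates, so none of these values is an error rate for the cell lines. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

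Differences between the 3' and 5' control probe sets on the log2 scale were 0.30 and 0.26 for GAPDH and 0.74 and 0.52 for ACTB in C4-2B and C4-2B-MDVR. The 3 probe sets for 18S ribosomal RNA were lower in C4-2B-MDVR by a mean of −0.49, from −0.70 to −0.17. Probe sets of 61 cytosolic ribosomal protein genes had a median difference of −0.0048. Bacillus probe sets, which had signal under the floor, had an SD of 0.13 over 27 probe sets.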

Results

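The series compared C4-2B, a human prostate cancer cell line that is sensitive to enzalutamide, with C4-2B-MDVR, a resistant line that, per the series description, was selected from C4-2B by long exposure to the drug. Enzalutamide is an antiandrogen used against prostate cancer. Per the labels both lines were grown in the same serum-containing medium and received no treatment before total RNA was isolated. Each line was measured on 1 Affymetrix expression array of 54675 probe sets, and the stated purpose was to find genes behind the resistance. Median intensity was 41.9 on the C4-2B array, with a range from 4.44 to 20839.7, and 43.5 on the C4-2B-MDVR array, with a range from 4.31 to 20630.6. Of 19775 named genes, 13437 were above the detection floor, which was the median log2 intensity of the brighter array (5.39 for C4-2B and 5.44 for C4-2B-MDVR). With 1 array per cell line there is no spread between replicates, so no p-value or SE can be given for any gene or gene group, and the number of arrays limits the precision. The title, source and cell line labels of the resistant sample name C4-2B-MDVR, but its free-text description names a docetaxel-resistant line, TaxR, and the description of the C4-2B sample calls that line docetaxel-sensitive. The cell line label was followed, so every direction below refers to the array labelled C4-2B-MDVR minus the array labelled C4-2B.

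The array labelled C4-2B-MDVR differed most from C4-2B by far lower KLK3, the gene for prostate-specific antigen, and by far higher DAPK1, a death-associated protein kinase. KLK3 had an intensity of 8379 in C4-2B and 172 in C4-2B-MDVR, a log2 difference of −5.61. DAPK1 went from 21.5, under the floor, to 1494, a log2 difference of 6.12 and at least 35.7-fold when the floor is taken for C4-2B. The other DAPK1 probe set above the floor differed by 3.16. In all, the measured difference was 2-fold or more for 426 higher genes (3.17%) and 470 lower genes (3.50%), and 93.3% of genes lay within 2-fold. Measured differences of 4-fold or more were found for 111 higher and 99 lower genes, and of 16-fold or more for 15 higher and 13 lower genes. These counts include genes whose dimmer value was under the floor. With such values raised to the floor, an alternative chosen after the data were seen, 371 genes were still 2-fold or more higher and 422 lower, 75 and 73 were 4-fold or more, and 5 and 8 were 16-fold or more. Below, "2-fold or more" refers to measured differences and "at least" to bounds against the floor.

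GCG, which encodes the glucagon precursor, had a measured log2 difference of 5.97 and was at least 12.7-fold higher. SYT4, a synaptotagmin of secretory vesicles, differed by 4.41, and BEX1, a small protein of brain and other tissues, by 4.86. These 2 genes and PLPPR1 (4.38) were above the floor on both arrays. The leucine-rich repeat protein LRRN1 (5.41) was at least 28.9-fold higher, and the heparan sulfate sulfotransferase HS3ST1 (4.20) at least 11.1-fold, with its other probe set above the floor at 0.67. The matrix protein MATN2 (4.55) was at least 9.69-fold higher, the laminin chain LAMB1 (4.34) at least 8.91-fold and the adhesion protein TENM2 (5.20) at least 8.65-fold. The adrenergic receptor ADRA2A (4.19) was at least 8.24-fold higher, the follistatin-like FSTL5 (5.59) at least 7.98-fold, TOX3 (4.09) at least 7.93-fold and the membrane glycoprotein CD200 (4.58) at least 4.60-fold. AKR1C3, an enzyme that makes testosterone from androstenedione, was at 4.02 and at least 4.01-fold higher. Values under the floor have no order, so the order of these genes by measured difference is not a ranking of their change. The 4 TOX3 probe sets above the floor ranged from −0.16 to 4.09, so its value depends on the probe set.

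On the lower side ELOVL7, which elongates long-chain fatty acids, had an intensity of 3442 in C4-2B and 114 in C4-2B-MDVR (−4.92). EPHA3, an ephrin receptor (−4.86), ST6GALNAC1 (−4.60) and CSTA (−4.60) were above the floor on both arrays as well. In C4-2B-MDVR, ST6GALNAC1 (log2 intensity 5.45) and CSTA (5.47) were barely above the floor of 5.44, so their differences are close to bounds. Apart from KLK3, the other genes of the 15 were under the floor in C4-2B-MDVR. The membrane protein TM4SF1 (−5.31) was at least 33.9-fold lower, the engulfment adaptor GULP1 (−5.38) at least 18.8-fold and ACADL, which oxidizes long-chain fatty acids (−4.47), at least 16.3-fold. PTGFR, the prostaglandin F receptor (−5.38), was at least 9.70-fold lower, TMEM47 (−4.82) at least 7.76-fold, PCDH7 (−4.52) at least 7.56-fold, CNKSR2 (−4.73) at least 7.19-fold and CADPS2 (−3.80) at least 6.57-fold. BMPR1B, a bone morphogenetic protein receptor (−4.57), was at least 3.41-fold lower and CNTN3 (−3.73) at least 2.24-fold. By bound, ELL2 (13.0-fold) and SLC45A3 (10.7-fold), which were above the floor on both arrays, came before several of these. PCDH7 probe sets above the floor ranged from −4.52 to −0.17 and those of GULP1 from −7.50 to −5.38.

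**Figure D1:**
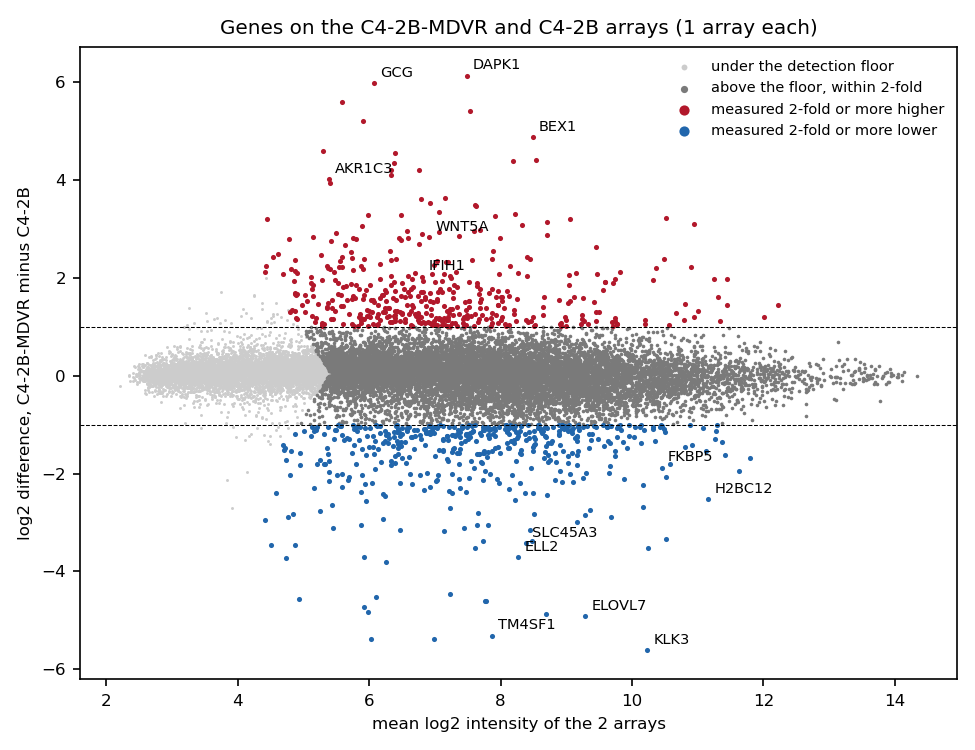
Log2 difference (C4-2B-MDVR minus C4-2B) against the mean log2 intensity of the 2 arrays, 1 point per gene, with dashed lines at 2-fold. Red marks the 426 genes measured 2-fold or more higher, blue the 470 measured 2-fold or more lower, dark grey genes within 2-fold and light grey genes under the detection floor, and KLK3 is the lowest point at −5.61.

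**Figure D2:**
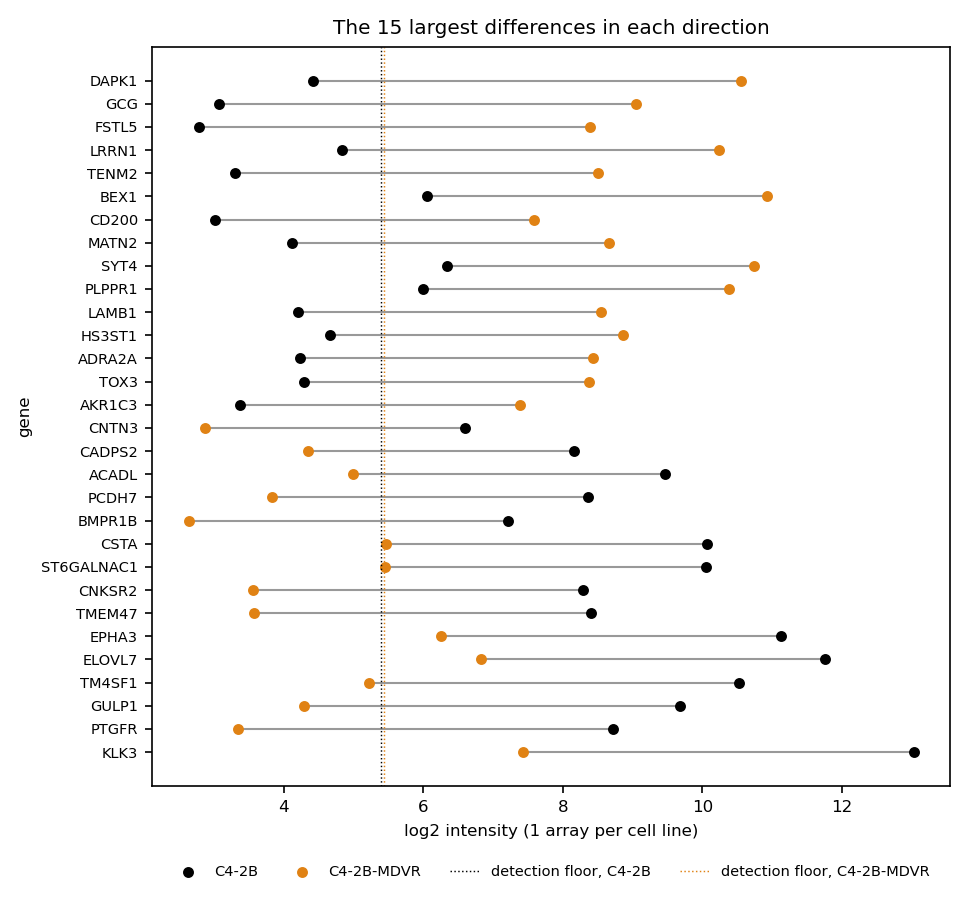
Log2 intensity in C4-2B (black) and C4-2B-MDVR (orange) of the 15 genes with the largest measured difference in each direction, 1 array per line. Dotted lines mark the detection floors of 5.39 and 5.44, and DAPK1 and KLK3 sit at the ends of the order with 6.12 and −5.61.

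Genes that androgen induces in prostate cells were lower as a group. Of 28 listed genes 22 were above the floor, 11 were 2-fold or more lower and 0 2-fold or more higher. Besides KLK3 these included ELL2, a transcription elongation factor (−3.70), the transporters SLC45A3 (−3.42) and ABCC4 (−2.74), and the kallikreins KLK15 (−2.22) and KLK2 (−2.10). FKBP5, a co-chaperone of steroid receptors, was at −1.88 and PMEPA1 at −1.76. The group was not uniform: TMPRSS2 differed by −0.27, KLK4 by 0.43 and TSC22D3 by 0.74. The list median of −1.06 was lower than that of all 10000 random lists of the same size and level. The 3 KLK3 probe sets differed by −6.24, −5.61 and −0.35.

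Androgen-repressed genes had no common direction. The median of the 5 genes above the floor was 0.21, at percentile 75.7 of random lists, with OPRK1, an opioid receptor, at 2.17 and UGT2B17 at −1.49. Both were under the floor on the dimmer array, and by bound (at least 1.42-fold and 1.58-fold) 0 members were beyond 2-fold. Steroid receptors and cofactors had a median of −0.05 over 12 genes (percentile 29.9). The coactivator NCOA1 (−1.06) was the 1 member of that list beyond 2-fold, and the pioneer factors FOXA1 (−0.08) and HOXB13 (0.05) were close to 0. NR3C1, the glucocorticoid receptor gene, was under the floor on both arrays.

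Lipogenic genes were lower too. Of 13 fatty acid synthesis genes above the floor 6 were 2-fold or more lower and 0 higher, among them ACSL1, an acyl-CoA synthetase (−1.49), malic enzyme ME1 (−1.37), the elongase ELOVL5 (−1.37) and the lipogenic transcription factor SREBF1 (−1.34). FASN, the fatty acid synthase, was at −1.19, but its other probe set above the floor was at 0.38, and SCD was at −1.07 with other probe sets of up to 0.22. Probe sets above the floor ranged from −1.37 to −0.014 for ELOVL5 and from −1.34 to −0.18 for SREBF1. The list median was −0.80, lower than in all random lists. With the mean of a gene's probe sets the median was −0.16 and the list no longer stood apart. Cholesterol synthesis genes did not stand apart, with a median of −0.15 over 18 genes (percentile 10.5) and TM7SF2 (1.11) the 1 gene beyond 2-fold.

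Enzymes of steroid hormone synthesis differed in both directions. The aldo-keto reductases AKR1C3 (4.02), AKR1C1 (2.94) and AKR1C2 (2.25) and the 3-beta-hydroxysteroid dehydrogenase HSD3B1 (1.84) were 2-fold or more higher, and the steroid sulfatase STS (−1.28) and the side-chain cleavage enzyme CYP11A1 (−1.11) 2-fold or more lower. Of the 18 genes above the floor these were 4 and 2, or 3 and 1 by bound, since HSD3B1 was at least 1.60-fold higher and CYP11A1 at least 1.23-fold lower. STS probe sets ranged from −1.28 to 0.05. The list median of 0.14 lay at percentile 81.9. The list mean of 0.54 stood apart at percentile 99.8. SRD5A1, a steroid 5-alpha reductase, differed by −0.44, and CYP17A1, HSD3B2 and HSD17B3 were under the floor on both arrays. AKR1C1 and AKR1C2 are near-identical and their probe sets share sequence, so their separate values are uncertain. HSD3B1 was 0.72 with the mean of its probe sets, which took in 1 that was under the floor on both arrays. Published work on this resistant line examined this pathway, so the list is not independent evidence.

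Enzymes that inactivate androgens were lower in part. UGT2B28 (−2.12) and UGT2B17 (−1.49), which conjugate androgens to glucuronic acid, were 2-fold or more lower, though UGT2B17 by a bound of at least 1.58-fold, and UGT2B15 differed by −0.42. The median of the 8 genes above the floor, −0.27, lay at percentile 3.23 and did not stand apart. The list did so with its mean (−0.50, percentile 1.59) and with values under the floor raised to it (percentile 2.41).

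Replication-dependent histone genes showed the lowest list median. Of 9 genes above the floor 8 were 2-fold or more lower, with H2AC6 at −2.99, H2BC12 at −2.52, H2BC4 at −2.37, the linker histone H1-2 at −2.24 and H2BC5 at −2.01. H3C8 (−0.57) was the exception among the 9. The median was −2.01, lower than in all random lists, and −1.65 with values under the floor raised to it. Over all 26 histone genes above the floor in the main histone cluster, counted after the data were seen, the median was −0.55. Of these, 10 were 2-fold or more lower and 16 within 2-fold. Several of the 16, such as H2AC4 (0.07), H1-3 (−0.03) and H4C13 (0.29), were near the floor on both arrays and could not show a drop. Brighter members within 2-fold included H2AC14 (−0.97) and H4C11 (−0.22). In H2BC12 the intensity went from 5493 to 958. G2/M genes, which act in mitosis, were slightly lower, with a median of −0.30 over 20 genes (percentile 0.37). CCNA2 (−1.37) and CENPE (−1.09) were the 2 beyond 2-fold, and the proliferation marker MKI67 differed by −0.37. G1/S genes had a median of −0.18 (percentile 5.56) with 0 genes beyond 2-fold and RRM2 lowest at −0.65, and at −1.01 in its other probe set.

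Interferon-stimulated genes and genes of antigen presentation were higher as groups. IFIT1 (2.15), the RNA sensor IFIH1 (2.02), the transcription factor IRF7 (1.41) and IFI6 (1.34) were 2-fold or more higher among 17 genes above the floor, and 0 were lower. By bound IFIT1 was at least 2.72-fold higher. The list median of 0.56 was higher than in all random lists. With values under the floor raised to it the median was 0.28 (percentile 99.1). The 5 members below 0 were HERC6 (−0.46), OAS3 (−0.28), MX2 (−0.23), RIGI (−0.22) and IFIT3 (−0.10). Genes of MHC class I presentation had a median of 0.61 over 12 genes, also higher than in all random lists, and included the peptide transporter TAP1 (0.92) and the immunoproteasome subunits PSMB8 (1.83) and PSMB9 (0.98). By bound PSMB8 was at least 2.26-fold and PSMB9 at least 1.22-fold higher. PSMB8 was the 1 gene of that list beyond 2-fold, and PSMB10 (−0.46), another immunoproteasome subunit, and ERAP1 (−0.05) were below 0. The names of the probe sets that stood for HLA-B (0.73) and HLA-F (0.63) mark shared sequence, so these values may not be separate readings.

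NF-kB genes were higher by a median of 0.52 over 13 genes above the floor (percentile 99.96). The chemokines CCL20 (2.69), CXCL8 (1.65) and CCL2 (1.07), lipocalin LCN2 (2.12) and TNFAIP2 (2.00) were 2-fold or more higher and 0 were lower. By bound 3 of these 5 remained, since CXCL8 was at least 1.27-fold and CCL2 at least 1.35-fold higher, and the list median was 0.34 (percentile 99.5). The other TNFAIP2 probe set above the floor differed by 0.24. NFKB1 (−0.45) and NFKBIA (−0.13) were not higher. Genes induced by DNA damage had a median of 0.62 over 17 genes, of which 15 were above 0, and this was higher than in all random lists. That list was fixed as targets of a transcription factor that responds to DNA damage. Its name is no finding of damage, which was not measured, and its member SESN2 (0.72) is also in the stress response list. CDKN1A, an inhibitor of cyclin-dependent kinases, was the 1 member 2-fold or more higher (1.05), and SESN1 (0.96), DDB2 (0.73) and POLH (0.76, with probe sets from −0.38) were among the others above 0.

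Oxidative stress genes, stress response genes and cancer-testis antigens stood apart by less. The NRF2 list had a median of 0.20 over 16 genes (percentile 98.4), and its 3 members beyond 2-fold in the higher direction were AKR1C1, AKR1C2 and AKR1C3, while ME1 was lower and NQO1 differed by −0.43. The integrated stress and unfolded protein response list had a median of 0.14 over 20 genes (percentile 97.6), with DDIT4 (1.10) the 1 gene beyond 2-fold, and HSPA5 at −0.24. Among 12 cancer-testis antigens SSX3 (3.29), SSX1 (2.81) and CTAG2 (2.63) were 2-fold or more higher and the median was 0.28 (percentile 99.4). These genes share sequence within families, and the 3 SSX3 probe sets above the floor ranged from −0.19 to 3.29. The cancer-testis call ended with a floor at the 25th percentile (0.11), with no floor (0.12) and without SSX3 (0.21). The calls of the NRF2 and stress lists ended when members shared with another list were left out, with medians of 0.15 and 0.12.

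**Figure D3:**
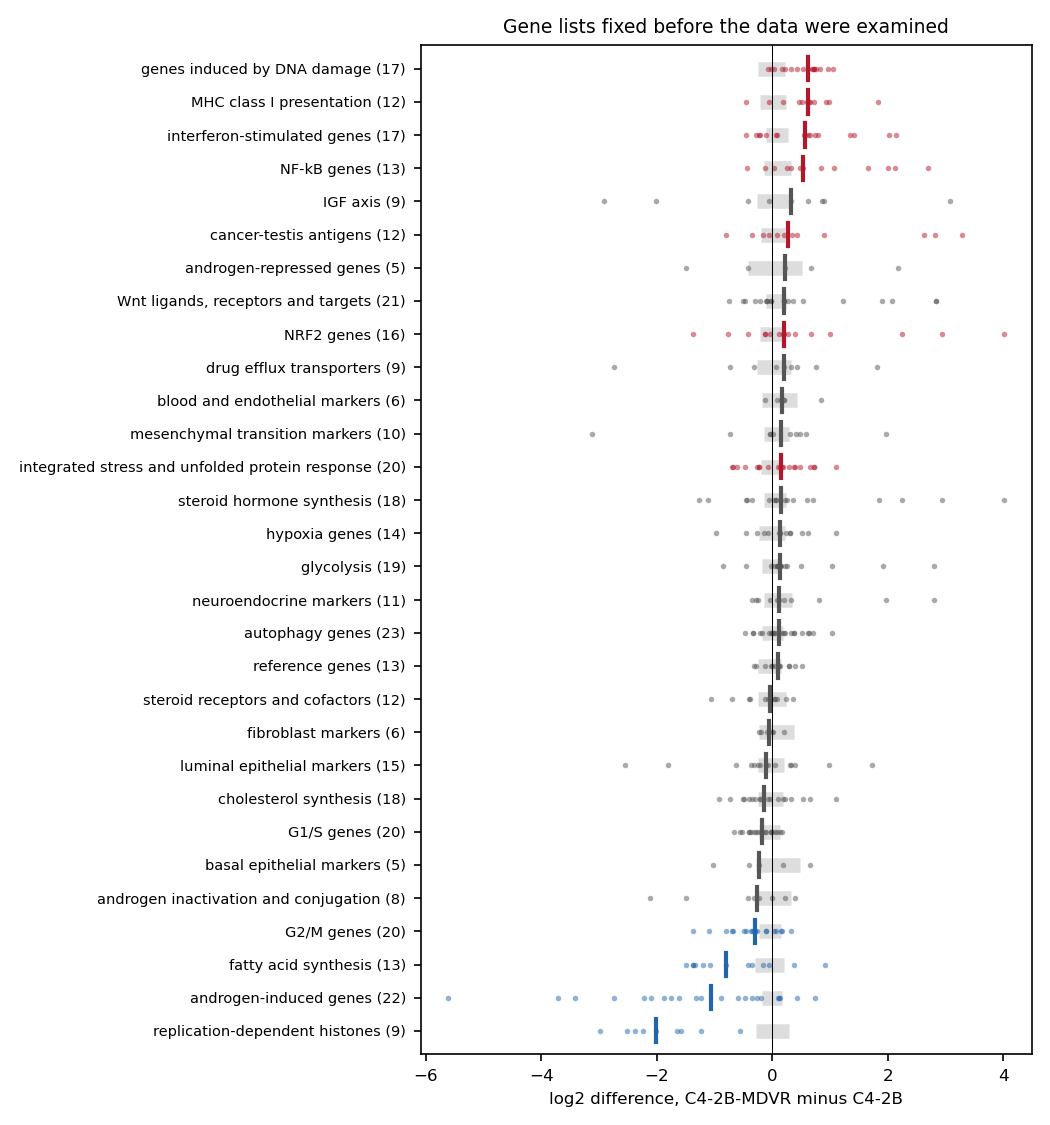
Log2 difference (C4-2B-MDVR minus C4-2B) of the members above the floor of 30 gene lists, with the number of members in parentheses. Points are genes, vertical bars list medians and grey bands the range of the medians of 10000 random lists without the outermost 2.5% at each end, with lists that stood apart in red or blue, from histones at −2.01 to genes induced by DNA damage at 0.62.

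Lineage marker lists did not stand apart in the main setting, though single members differed by 2-fold or more. Neuroendocrine markers had a median of 0.12 over 11 genes (percentile 53.2), with the enolase ENO2 at 2.80 and neurotensin NTS at 1.96. Both were under the floor in C4-2B, and by bound they were at least 5.52-fold and 3.39-fold higher. Synaptophysin SYP differed by −0.35, and chromogranin CHGA was under the floor on both arrays. Luminal markers had a median of −0.10 over 15 genes (percentile 19.1), with AGR2 (−2.55) and MSMB (−1.80, by a bound of at least 1.58-fold) lower and ELF3 (1.73) higher, and the cadherin CDH1 at −0.31. Mesenchymal markers had a median of 0.16 over 10 genes (percentile 76.4), with SNAI2 at −3.12, FN1 at 1.97 and vimentin VIM at −0.73. SNAI2 was under the floor in C4-2B-MDVR, and by bound it was at least 2.97-fold lower. With the mean of a gene's probe sets the luminal list (−0.22) and the mesenchymal list (0.41) stood apart, and with values under the floor raised to it the mesenchymal median was 0.068. Basal markers had a median of −0.23 over 5 genes (percentile 3.64) with ITGA6 at −1.02, and a median of 0.00030 with values under the floor raised to it. Fibroblast markers (median −0.05 over 6 genes) and blood and endothelial markers (0.17 over 6 genes) held 0 genes beyond 2-fold. COL1A1 in the fibroblast list was at −0.23, but 2 of its other probe sets above the floor were at 1.07 and 1.20.

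Signalling and metabolic lists were mixed as well. In the Wnt list DKK1 (2.83), WNT5A (2.83), LEF1 (2.07), FZD2 (1.90) and FZD7 (1.23) were 2-fold or more higher and 0 lower. FZD3 was counted at −0.75, but its probe sets above the floor ranged from −1.12 to −0.08. The other probe set above the floor was at 0.76 for FZD2, 1.87 for FZD7 and 2.39 for WNT5A. DKK1 was under the floor in C4-2B, and by bound it was at least 2.26-fold higher. The Wnt list median of 0.20 over 21 genes lay at percentile 93.3. In the IGF axis the binding protein IGFBP3 (3.07) was higher and the receptor IGF1R (−2.92) and the ligand IGF1 (−2.02) lower. IGF1R was under the floor in C4-2B-MDVR, and by bound it was at least 4.69-fold lower. The IGF list had a median of 0.32 over 9 genes (percentile 96.8). Probe sets above the floor ranged from −4.76 to −1.04 for IGF1R and from −5.38 to −1.71 for IGF1. Glycolysis genes had a median of 0.13 over 19 genes (percentile 97.2), with ENO2, ALDOC (1.92) and PFKP (1.04) beyond 2-fold. By list mean the Wnt list (0.48, percentile 99.6) and the glycolysis list (0.34, percentile 99.8) stood apart. Hypoxia genes (0.14 over 14 genes), autophagy genes (0.11 over 23 genes) and drug efflux transporters (0.20 over 9 genes) did not stand apart. ABCB11 (1.82, by a bound of at least 2.17-fold) was higher in the transporter list and ABCC4 lower. ABCB1, the main docetaxel exporter, was under the floor on both arrays. Reference genes had a median of 0.10 over 13 genes and ranged from −0.32 for SDHA to 0.51 for B2M.

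Of the 30 lists 11 stood apart, 7 higher and 4 lower, where lists of unrelated genes would give 1.5 by chance. Genes of a fixed list can be regulated together, and some lists share genes or probe sequence. Their medians can therefore spread more than random medians, and 1.5 may be too low for them. Bacterial and phage hybridization controls differed by a mean of 0.07 between the arrays with an SD of 0.12 over 18 probe sets, which covers hybridization only and no spread between cultures. Of 404 genes beyond 2-fold that had another probe set above the floor, 376 (93.1%) had the same direction in that probe set and 194 (48.0%) were 2-fold or more the same way, and none was 2-fold or more the opposite way. Some of the named calls were lost under other settings. With each array centred on its median CDKN1A was at 0.99 and PFKP at 0.98, with quantile normalization NCOA1 was at −0.99 and ITGA6 at −0.98, and with loess CCL2 was at 0.99. With the mean of a gene's probe sets IFIH1 was at 0.90, KLK15 at −0.80, ELF3 at 0.98, PFKP at 0.73, STS at −0.55, ELOVL5 at −0.69 and SREBF1 at −0.76. That mean took in probe sets under the floor: IFIH1 had 1 of 3 probe sets above it and KLK15 had 2 of 4.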

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

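All tests on stretches of neighbouring genes, the ABCB1 test and the G1/S test of the histone genes were chosen after the result was seen, and the tests of other RNAs without a poly(A) tail and of the histone cluster were set before their values were seen.

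Probe sets without a listed gene, which the comparison does not use, also differed between the arrays, and were picked out as signal in data outside the main measurement. Of 3299 such probe sets above the floor 39 (1.18%) were 2-fold or more higher and 130 (3.94%) 2-fold or more lower in C4-2B-MDVR. There are no control samples to set these counts against.

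Replication-dependent histone genes of the fixed list were lower, with a median of −2.01. Over all 26 histone genes of the main cluster the median was −0.55 with 16 within 2-fold, several of them too near the floor to show a drop. The variant histone gene H2AJ, singled out after its value was seen, was at −3.51. Fewer cells in S phase stays open: the G1/S list had a median of only −0.18 and a lowest member of −0.65, but a second probe set of that member, RRM2, was at −1.01, past the bound set for it. Weaker labelling of RNA without a poly(A) tail stays open: 8 other such RNAs had a median of 0.18 (from −1.19 to 0.95), above the −1 set beforehand as the bound against it, but most are small RNAs whose probe sets may read host transcripts, 18S ribosomal RNA was lower by a mean of −0.49 with all 3 probe sets below 0, and the labels name a whole-transcript labelling kit while the probe annotation is of a 3' array. Loss of the main histone gene cluster is argued against by the 12 other protein-coding genes between its histone genes, from HFE to ZNF184, which had a median of 0.25. A difference between the resistant and the sensitive line in histone transcripts, or in their tails, remains a hypothesis that these arrays cannot separate from a difference between 2 cultures.

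Neighbouring genes tended to differ together: over 13399 genes in chromosome order adjacent genes had a Pearson's r of 0.16, against at most 0.03 in 1000 shuffled orders. Windows of 30 genes with medians outside all shuffles of a first draw of 1000 formed 5 lower stretches of 452 genes, the longest from MPHOSPH8 to ERCC5 (181 genes, median −0.52) and from OSTC to TUBB7P (150 genes, −0.53), and 2 higher stretches, from SP4 to FKBP14 (0.35) and from SH3BGRL to TSC22D3 (0.28). A new stretch began where such windows no longer overlapped. Stretches can therefore be parts of the same larger region, and their number is no count of independent regions. A level-dependent bias is argued against for the lower stretches, since 5 of 5 stayed outside 2 independent draws after a loess correction. Without the correction the stretch from SP4 to FKBP14 was outside both draws (0 of 2000 shuffles as extreme). The stretch from SH3BGRL to TSC22D3 was then outside the first only (1 of 2000). After the correction 2 of 2 higher stretches stayed outside the first draw and 0 outside both, so they are marginal and depend on the draw. The first and second draw were both kept because the choice of draw was seen to change this result. A different number of gene copies cannot be told apart from shared regulation, since no DNA was measured, and medians of the size a change of 1 copy gives (4 of 5 lower and 1 of 2 higher stretches) say nothing for it because the stretches were picked by size. TSC22D3 of the androgen-induced list ends a stretch, so members of the fixed lists can lie in stretches. The list and gene results above were not separated from these stretches.

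The free-text description of the array labelled C4-2B-MDVR names a docetaxel-resistant line, so the possibility of a mixed-up description was weighed. A docetaxel-resistant line with raised ABCB1, the main docetaxel exporter, is argued against by the 2 ABCB1 probe sets, of which the highest difference was −0.085, both under the floor on both arrays. A docetaxel-resistant line without raised ABCB1 stays open, and no biological explanation was tested for this mismatch of labels.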

How the results depend on the processing

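The alternatives without probe sets whose names mark shared sequence or several transcripts (306 higher and 463 lower genes), with all probe sets of a gene 2-fold or more the same way (325 and 316) and with values under the floor raised to it (371 and 422, and 13 lists standing apart) were chosen after seeing the data. No gene or list call turned to the opposite call; values close to 0 could change sign, as the basal median did with values raised to the floor (0.00030). Of 1000 comparisons of named genes with an alternative 971 kept their side of 2-fold, 25 lost it and 4 gained it. Counts of genes higher and lower moved by over 1.5 times with thresholds of 1.5-fold (1110 and 1252) and 3-fold (195 and 161), by construction, with the mean of a gene's probe sets (302 lower) and with a floor at the 75th percentile (280 higher, fewer genes tested). Lists standing apart numbered 11, and 9 to 14 under alternatives. The NRF2 call was lost with medians of 0.19 (quantile), 0.18 (loess), 0.14 (mean of probe sets), 0.19 (75th percentile floor), 0.20 (unmatched) and 0.15 (without shared genes). The stress response call was lost at 0.10 (mean of probe sets), 0.13 (75th percentile floor), 0.14 (5 bins, and unmatched), 0.10 (list mean), 0.13 (without the most different member) and 0.12 (without shared genes). The cancer-testis call was lost at 0.11 (25th percentile floor), 0.12 (no floor) and 0.21 (without the most different member), and the fatty acid synthesis call at −0.16 (mean of probe sets). Calls appeared for luminal markers at −0.22 and mesenchymal markers at 0.41 (mean of probe sets), Wnt genes at 0.21 (25th percentile floor) and 0.48 (list mean), the IGF axis at 0.32 (5 bins, unmatched, and values raised to the floor), androgen inactivation at −0.27 (values raised to the floor), G1/S genes at −0.18 (unmatched), and, with list means, steroid synthesis at 0.54, androgen inactivation at −0.50 and glycolysis at 0.34. The androgen-induced, G2/M, histone, interferon, NF-kB, DNA damage and MHC class I lists stood apart under every alternative run. Beyond the construction of each alternative the cause was not tested. No paired analysis was possible because each line has 1 array. Signal near the floor limits genes that are dim on both arrays.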

Other observations

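The families below were chosen after their values were seen, and no test of them was planned. BEX, TCEAL and ARMCX genes, which neighbour each other in the reference gene order, had a median of 0.67: 7 of 15 above the floor were 2-fold or more higher, none was 2-fold or more lower and the others lay within 2-fold. BEX1 (4.86), BEX5 (3.45), TCEAL3 (1.49) and BEX4 (1.41) were among them and above the floor on both arrays, while ARMCX4 (3.27) and TCEAL2 (2.24) were under it in C4-2B, and TCEAL1 (0.22) and TCEAL4 (0.24) differed least. They lie in the higher stretch from SH3BGRL to TSC22D3, which depended on the draw of shuffled orders.

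Cytoskeletal and vesicle genes differed by single members. Of 11 tubulin genes above the floor TUBA1A (3.62), TUBB4A (2.02) and TUBB6 (1.60) were 2-fold or more higher, while the abundant TUBA1B (−0.02) and TUBB (0.14) differed little. Of 11 synaptotagmins SYT4, SYT17 (2.17) and SYT13 (1.54) were 2-fold or more higher. Of 4 IFITM genes above the floor, IFITM1 (1.19), IFITM3 (1.11) and IFITM2 (1.06) were 2-fold or more higher, and IFITM10 (0.28) was within 2-fold. Of 6 MHC class II genes HLA-DQB1 (1.25) was the 1 beyond 2-fold, with a median of 0.61 and 0 lower.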
